A study of Mus musculus with 8 samples.

How the data were processed

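Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse induced pluripotent stem cells of a clonal FUCCI2 line. FUCCI2 is a pair of fluorescent reporters whose abundance follows the phase of the cell cycle. Per the labels, the cells grew on irradiated feeder cells with serum, LIF and 2 inhibitors of MEK and GSK3, and each library started from 50000 cells. There were 8 libraries in 4 groups of 2 replicates, A and B. Mitotic cells were collected by shake-off after 6 hours in nocodazole at 200 ng/ml, which blocks spindle assembly. Further cells were collected 1 and 3 hours after release into fresh medium, and asynchronous cells were left untreated. The labels give total RNA as the molecule and a transcriptomic library source, which conflicts with their titles and protocol, and the titles and protocol were followed. They do not say whether the replicates came from separate cultures.

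The deposited data analysed here were 1 list of regions for the whole series, called the atlas below. The authors deposited a chromosome, a start and an end for each region, in base pairs, without a read count, score, strand or name and without any value per library. The submitters' processing notes name cutadapt, Bowtie2, Picard, SAMtools, bedtools and MACS2 version 2.1.1, and the build GRCm38 (mm10). The parameters of these tools, the shift of reads for the Tn5 insertion, the removal of blacklisted regions and the way in which regions from different libraries were merged are not given in the sources used here. If the regions of every library were kept, the list counts a region open in a single library like a region open in all of them. Without a value per library, the depth of each library is unknown, and no region could be assigned to a group. The comparisons between groups fixed before the data were examined, which needed a value per library, were not made.

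The atlas was set against gene spans of the same build, GRCm38.p6, which held 49943 genes, 21887 of them protein-coding. Only the outer limits of each gene were used here, with no strand, transcript, exon or sequence. The plan had named promoters, exons and introns. In their place, a region counted as lying at a gene end if at least 1 bp of it fell within 1 kb of either outer limit of a protein-coding gene. One of these limits is the outermost start of the gene and the other its far end, and they were not told apart. The remaining regions were distal, and were divided into those touching a protein-coding gene and those between such genes. A planned search for sequence motifs was not made without a genome sequence. Coordinates are given from 1.

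The share of regions at gene ends was compared with 1000 random placements of the same regions, each on its own chromosome with its own width, between the first and the last gene or region of that chromosome. Assembly gaps were not excluded from this span. The test was one-sided for enrichment, and the division into 3 classes was tested in both directions with Benjamini-Hochberg adjustment. For 17 gene lists written before the data were examined, the share of genes with a region at an end was compared with all other protein-coding genes by Fisher's exact test, two-sided. The lists covered core pluripotency genes, LIF, Wnt and FGF signalling, ectoderm and neural, mesoderm, endoderm, trophoblast, feeder fibroblast and adult tissue genes, housekeeping, G1/S, G2/M, chromatin architecture, immediate early, Hox, replication-dependent histone, olfactory receptor and vomeronasal receptor genes. The mean number of distal regions within 50 kb of either end was compared with 100000 random lists of the same size, two-sided. Random lists were drawn from the same classes of local gene density and of gene length, with 5 classes of each. Length was added to the plan because both ends of each gene were used. Both tests were adjusted over the 17 lists by Benjamini-Hochberg at 0.05. Neighbouring genes share regions, so genes are not independent replicates and these p-values describe this atlas only. Intervals of shares are 95% Wilson intervals and cover counting error only. Medians of width were compared by permuting class labels 100000 times. Regions per Mb were correlated with protein-coding genes per Mb over 20 chromosomes with 100000 permutations. Named genes were the core pluripotency genes, of which 1 is not reported by name here, the 2 members of each other list with the most distal regions and 1 member with none, the 10 protein-coding genes with the most distal regions, and those nearest to the 5 widest regions. Other genes named were chosen after their values were seen.

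The overlap and test code was tested on simulated data. On small random sets of genes and regions, it gave 0 disagreements with a direct count. Of 50 simulated lists made to differ, 50 were recovered by each of the list tests, and of 50 unchanged lists the gene-end test called 3 and the distal test 2. The lists made to differ gained a region at an end of most genes and several nearby regions for every gene. All simulated lists held genes drawn at random, on an atlas of randomly placed regions. These counts therefore do not measure power or error for smaller differences or for lists of neighbouring genes. Alternatives changed the distance that defines a gene end, the required overlap, the window, the matching, the background and the set of regions. The stricter set held the widest 57821 regions, those of at least 152 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.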

Results

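ATAC-seq was performed on mouse FUCCI2 induced pluripotent stem cells arrested in mitosis, released from arrest for 1 or 3 hours, or left asynchronous, with 2 libraries in each of the 4 groups. The series addresses how transcription and chromatin architecture change as cells leave mitosis. The atlas analysed here is 1 list of accessible regions for the whole series. How each of the 8 libraries contributed to it is not given in the sources used here. The measurements below therefore describe where chromatin was accessible in at least part of the series. They give no change between arrested, released and asynchronous cells. The depth of the libraries is unknown.

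The atlas held 76872 regions on 21 chromosomes. They covered 28.1 Mb, or 1.04% of the 2704 Mb between the outermost genes or regions of the chromosomes. The median width was 281 bp, with quartiles of 152 and 498 bp and a range of 73 to 3218 bp. At the lower limit, 3054 regions (3.97%) were exactly 73 bp wide, against 224 that were 1 bp wider. No regions overlapped, and neighbouring regions lay at least 163 bp apart, with a median gap of 13518 bp. The widest region, at chromosome 1, 24612854 to 24616071, touched the pseudogene Gm10925 and lay 24.9 kb from the nearest protein-coding gene, Col19a1. The next widest regions, of 2971, 2677, 2468 and 2416 bp, had Mctp2, Smgc, Cntn1 and Mageb5 as their nearest protein-coding genes, at distances of 343, 45, 57.8 and 58.1 kb. Pseudogenes lay closer to those of 2971, 2468 and 2416 bp, namely Rpl17-ps10 at 0.958 kb, Gm18979 at 27.3 kb and Gm46678 at 9.3 kb. For the region of 2677 bp, Smgc was the nearest gene of any type.

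Accessible regions were concentrated at the ends of protein-coding genes. Of the atlas, 15779 regions (20.5%) lay within 1 kb of a gene end, against 3.61% ± 0.0671 (SD over 1000 random placements), a 5.68-fold enrichment (one-sided permutation p = 0.000999, the smallest these placements can give). A region lay at an end of 13567 of the 21887 protein-coding genes (62.0%). For 11713 genes (53.5%) this was at a single end and for 1854 (8.47%) at both. When the same genes were moved by 20 kb to either side, 20.1% and 20.2% had a region at an end. Regions inside genes and away from their ends made up 35.8% of the atlas (27507 regions), slightly below the 38.1% ± 0.171 of the placements. Regions between genes made up 43.7% (33586 regions), against 58.3% ± 0.177. The adjusted permutation p was 0.002 for each of the 3 classes, two-sided. The 3 shares make up the whole atlas, so the excess at gene ends by itself lowers the others. The share inside genes was 0.940 times that of the placements and the share between genes 0.749 times. Among distal regions, those inside genes were thus more frequent relative to those between genes than in the placements, a relation not itself tested. The median distance from a region to the nearest gene end was 13.4 kb, and 20252 regions (26.3%) lay more than 50 kb away.

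**Figure D1:**
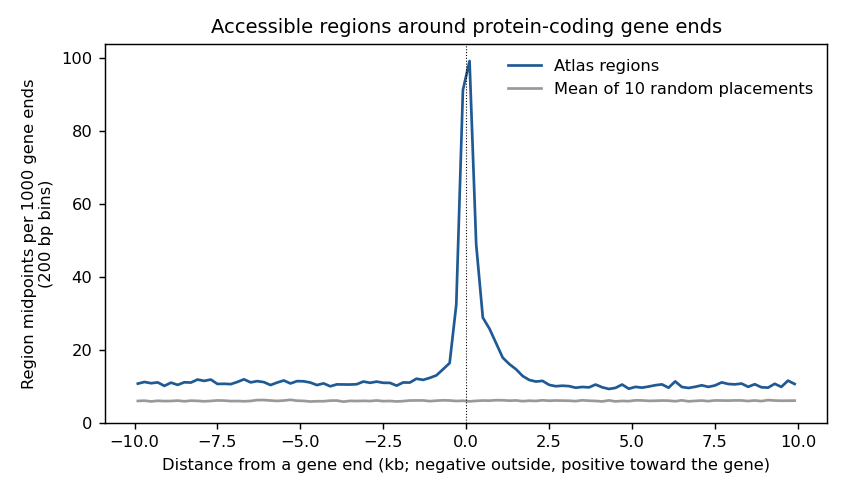
Region midpoints per 1000 gene ends (vertical axis) in 200 bp bins against the distance in kb from the outer ends of protein-coding genes (horizontal axis, negative outside the gene), for the atlas (blue) and the mean of 10 random placements (grey). The atlas reaches 99.2 midpoints per 1000 ends in the first bin inside the gene and 91.2 in the first bin outside, against 5.88 and 6.04 for the placements.

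Regions at gene ends were also wider. Their median width was 525 bp (quartiles 272 and 790 bp), against 246 bp (142 and 415 bp) for all other regions. The difference of 279 bp had a two-sided permutation p of 1e-05, the smallest that the permutations can give. Regions inside genes and between genes had similar medians, of 241 and 252 bp.

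Pluripotency genes were marked at their ends and surrounded by distal regions. Of the 24 core pluripotency genes, 22 (91.7%, 95% interval 74.2 to 97.7%) had a region at an end, against 62.0% of other protein-coding genes (Fisher's exact test, adjusted p = 0.0040). The reprogramming factor genes Sox2, Klf4 and Pou5f1 were among them. A region of 920 bp spanned the lower end of Sox2 at chromosome 3, 34649209 to 34650128, and a region of 1019 bp spanned the upper end of Klf4 at chromosome 4, 55532294 to 55533312. At Pou5f1, which encodes Oct4, the regions at the ends were narrower, of 141 bp at chromosome 17, 35505857 to 35505997, and of 73 bp at 35509999 to 35510071. Wider regions of 375, 655 and 918 bp lay 1.13, 1.65 and 5.47 kb from the nearer end of Pou5f1. Nanog, which encodes a homeodomain factor of the pluripotency network, had regions of 447 and 619 bp at its ends and a wider one of 1118 bp at chromosome 6, 122702044 to 122703161, 4.33 kb from the gene. The exceptions were Esrrb and Nr5a2, both nuclear receptors, which had no region within 1 kb of an outer end but 16 and 7 regions touching the gene. The widest of these was 779 bp in Esrrb and 536 bp in Nr5a2.

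**Figure D2:**
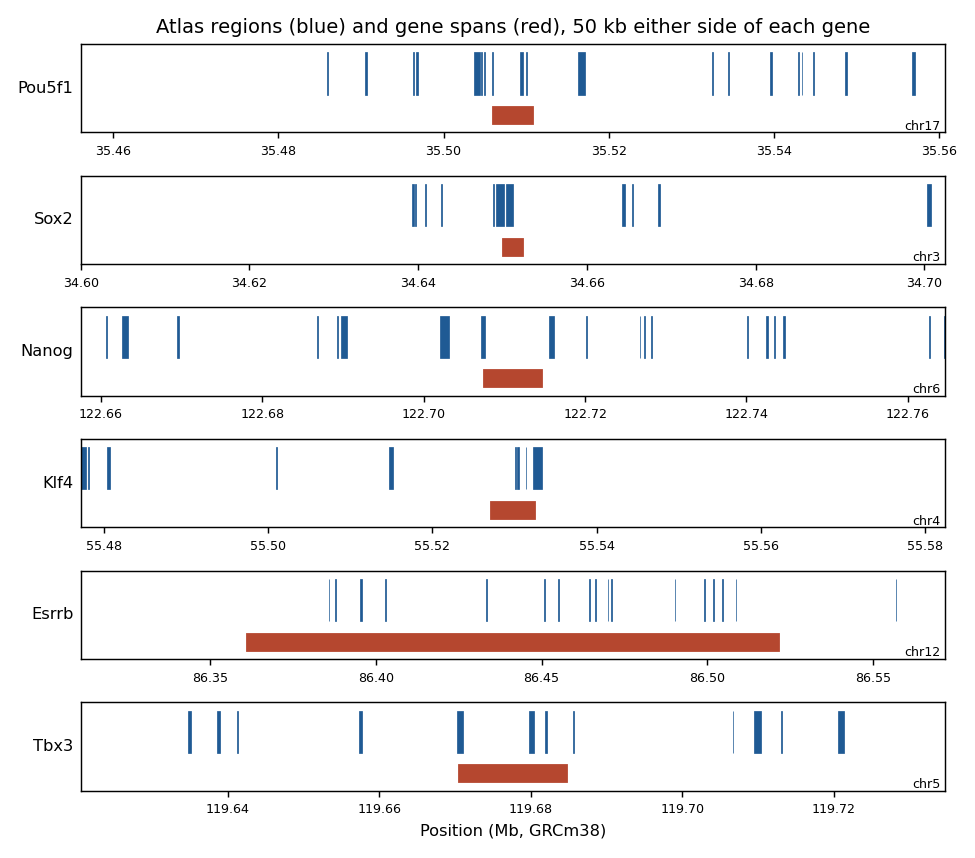
Atlas regions (blue) and gene spans (red) around 6 core pluripotency genes, with 50 kb shown on either side of each gene and the GRCm38 position in Mb on the horizontal axis. Pou5f1, Sox2, Nanog, Klf4 and Tbx3 have regions at a gene end, and Esrrb has 16 regions within the gene and none within 1 kb of its ends.

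The core pluripotency genes had on average 9 ± 3.08 distal regions within 50 kb (SD, n = 24 genes), 2.25 times the 4.01 of random lists matched on gene density and length (permutation test, adjusted p = 0.000113). Over all protein-coding genes the median was 4 distal regions, with quartiles of 2 and 6. Klf5, Nanog and Tet1 had 14 each, Dppa3 and Prdm14 had 12, Pou5f1 and Fbxo15 had 11, and Esrrb, Mycn, Tbx3 and Zfp42 had 10. Tfcp2l1 had 9, and Fgf4, Klf4, Nr5a2, Sox2, Tdgf1 and Utf1 had 8. Lower counts were found for Sall4 with 7, Klf2 with 6, Lin28a with 5, Dppa4 with 4 and the X-linked Nr0b1 with 2. Genes of LIF, Wnt and FGF signalling, the pathways that the culture medium acts on, were similar. A region lay at an end of 20 of 22 (90.9%, adjusted Fisher's exact p = 0.0058), and their mean of 8.14 ± 4.03 distal regions was 1.91 times that of matched lists (adjusted permutation p = 0.0021). Tcf7l1, a transcription factor of the Wnt pathway, had 17 distal regions and 20 touching the gene, and Lef1 had 16 distal regions.

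None of the ectoderm and neural, mesoderm, endoderm and trophoblast lists differed from other genes in the share with a region at an end. The ectoderm and neural list had 14 of 20 genes with a region (70%, adjusted Fisher's exact p = 0.646), among them Sox1, Neurog1 and Nkx2-2. The mesoderm list had 10 of 20 (50%, adjusted Fisher's exact p = 0.404), with T and Mesp1 among those with a region and Pax2 and Meox1 among those without. The trophoblast list had 9 of 16 (56.3%, adjusted Fisher's exact p = 0.646) and the endoderm list 7 of 18 (38.9%, adjusted p = 0.0685). In the stricter set of wider regions the endoderm share of 33.3% was lower than that of other genes (adjusted Fisher's exact p = 0.0437). When a region anywhere in the gene was counted as well, a setting chosen after seeing the data, the ectoderm and neural share was 95%, against 63.1% of matched lists (adjusted permutation p = 0.0012).

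Distal regions were more frequent near trophoblast genes, with a mean of 6.81 ± 3.58 against 4.07 in matched lists (adjusted permutation p = 0.027, n = 16 genes). Tead4 had 15 and Gcm1, which encodes a placental transcription factor, had 10. This call was lost with windows of 100 kb (adjusted permutation p = 0.0836) and with matching on gene density alone (adjusted p = 0.0731). The other lineage lists did not differ, with 4.40 against 3.89 for ectoderm and neural genes (adjusted permutation p = 0.580), 4.50 against 3.66 for mesoderm (adjusted p = 0.338) and 4.61 against 4.22 for endoderm (adjusted p = 0.657). Nkx2-2 and Zic1 each had 9 distal regions, Pax2 had 12, Meox1 had 7, Hnf4a had 11 and Ttr had 8, while Cer1, a secreted endoderm antagonist, had none and no region at its ends. Of the Hox genes, 21 of 39 had a region at an end (53.8%, adjusted Fisher's exact p = 0.392), and their mean of 3.72 distal regions was close to the matched mean of 3.74 (adjusted permutation p = 1). Hoxd8 and Hoxd9 had 7 distal regions each and Hoxb1 had none.

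Regions at an end were less frequent than in other genes for the feeder fibroblast, adult tissue and receptor lists. Of the feeder fibroblast genes, 8 of 22 (36.4%, interval 19.7 to 57.0%) had a region at an end, below other genes (adjusted Fisher's exact p = 0.0225). These were Col1a1, Col5a1, Fbn1, Fn1, Snai2, Tagln, Twist1 and Twist2, while Col1a2, Col3a1, Dcn, Lum, Pdgfra, Postn and Thy1 were among the 14 without. This call was lost when ends were extended to 2 kb, at 50% (adjusted Fisher's exact p = 0.157), and when regions anywhere in the gene were counted (adjusted permutation p = 0.246). Of the adult tissue genes, 5 of 24 (20.8%) had a region at an end, namely Apoa2, Ckm, Pomc, Sftpc and Tnnt3 (adjusted Fisher's exact p = 0.000195). The same genes moved by 20 kb gave 16.7%. For the feeder fibroblast genes the move gave 11.4%, farther below their observed share. Distal means of 3.55 for feeder genes and 3.17 for adult tissue genes did not differ from the matched means of 4.53 and 4.23 (adjusted permutation p = 0.278 and 0.160). Col1a1, Loxl1 and Slc12a1 had 8 distal regions each and Ckm had 9, while Sftpc had none. The olfactory receptor genes had a region at an end in 32 of 1106 cases (2.89%, odds ratio 0.0160) and the vomeronasal receptor genes in 7 of 353 (1.98%, adjusted Fisher's exact p = 2.1e-134). Moved by 20 kb, they gave 6.01% and 6.94%. These receptor genes formed 85 and 106 runs of neighbouring genes, and Fisher's exact test counts neighbours as independent. Their distal means of 1.47 and 1.75 were below the 3.40 of matched lists in each case (adjusted permutation p = 0.000113). The highest counts among them were 10 for Olfr221, 9 for Olfr1423, 11 for Vmn1r3 and 10 for Vmn1r238, and Olfr1 and Vmn1r104 had none.

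Housekeeping and cell cycle genes had a region at an end in nearly every case. The housekeeping, G1/S and chromatin architecture lists each had 22 of 24 genes with a region (91.7%, adjusted Fisher's exact p = 0.0040). All 24 G2/M genes had one, among them Ccnb1, Plk1 and Cdk1 (adjusted Fisher's exact p = 7.3e-05). The G1/S share was 79.2% in the stricter set, where the call was lost (adjusted p = 0.0726), and the chromatin architecture share did not differ from matched lists, which reached 73.2% (adjusted permutation p = 0.0720). Immediate early genes had a region in 19 of 20 cases (95%, adjusted Fisher's exact p = 0.0040) and replication-dependent histone genes in 63 of 63 (adjusted p = 7.8e-13). The 63 histone genes formed 5 runs of neighbouring genes, and the gene-end test was not repeated with neighbours counted as 1 gene. The histone genes are short, with a median length of 0.492 kb, and 90.5% of them (57 genes) had a region at both ends, which in 30 of the 57 was 1 region within reach of both. Without regions in 100 kb windows that held 20 or more, a setting chosen after seeing the data, the histone share was 77.8% (adjusted Fisher's exact p = 0.016). Genes inside these windows stayed in the list and lost their regions by construction. The lower share therefore does not describe histone genes outside the windows.

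**Figure D3:**
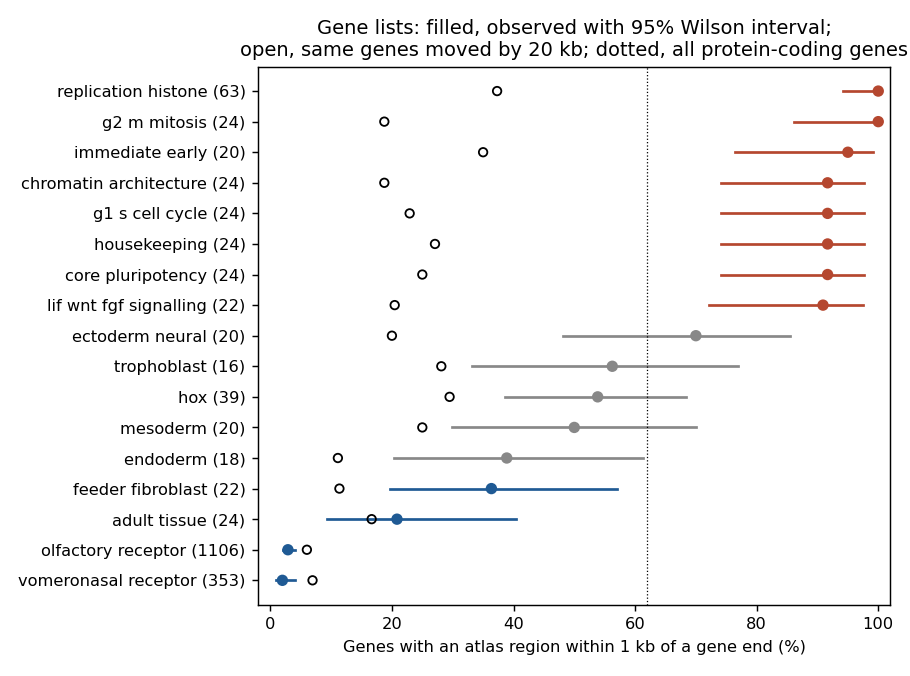
Share of genes with an atlas region within 1 kb of a gene end, in percent, for the 17 gene lists, with the number of genes in brackets, 95% Wilson intervals as lines and the share after moving the genes by 20 kb as open circles. Red lists are above and blue lists below other protein-coding genes after adjustment, grey lists did not differ, and the dotted line marks the 62.0% of all protein-coding genes.

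Distal regions were more frequent than in matched lists near immediate early, housekeeping and G1/S genes, and not near G2/M and chromatin architecture genes. The immediate early genes, which respond to growth signals within minutes, had a mean of 7.60 ± 4.26 distal regions against 3.42 in matched lists (adjusted permutation p = 0.0021), with 15 at Junb and 14 at Fosb and none at Fosl1. The housekeeping genes had 7 ± 4.42 against 3.97 (adjusted permutation p = 0.0021), with 22 at Actb and 12 at Eef1a1. The G1/S genes had 6.67 ± 3.51 against 4.45 (adjusted permutation p = 0.016), with 15 at Ccnd3, which encodes cyclin D3, and 12 at Cdkn1a, which encodes the inhibitor p21. With windows of 25 kb the G1/S call was lost (adjusted permutation p = 0.0768). The G2/M genes did not differ from matched lists, at 3.83 against 4.39 (adjusted permutation p = 0.572), with 9 at Cdk1 and Tpx2 and none at Ccna2. The chromatin architecture genes did not differ either, at 5.54 against 5.33 (adjusted permutation p = 0.818), with 16 at Rad21 and 14 at Stag1, both subunits of cohesin. Histone genes had 4.68 against 3.01 (adjusted permutation p = 0.000255), with 12 at H2bc9 and H3c7 and none at H2ac6. Without the regions of crowded windows, but with the genes in them kept, the histone mean was 2.95, against 2.95 in matched lists (adjusted permutation p = 0.990). Histone genes in those windows lost nearby regions by construction, so this loss of the call does not show the mean of the other histone genes. The call was also lost with neighbouring genes counted as 1 (adjusted permutation p = 0.189), with matching on density alone (0.269) and without matching (0.631). The difference between lists was not itself tested.

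**Figure D4:**
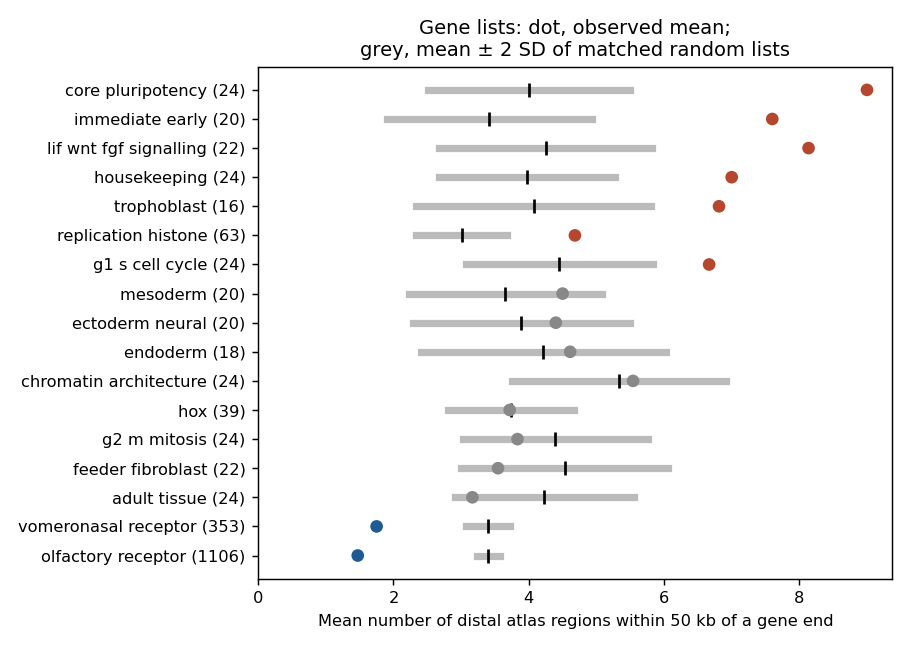
Mean number of distal atlas regions within 50 kb of a gene end for the 17 gene lists (dots, number of genes in brackets), with the mean of matched random lists (black mark) and 2 SD of these lists to either side (grey bar). Red dots are higher and blue dots lower than matched lists after adjustment, and the core pluripotency list is the farthest to the right at 9.

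Over all protein-coding genes, those with the most distal regions were Sfi1 with 55, Gm10354 and Speer4d with 51 each, Gm38510 with 49, Gm7592 with 47, Gm52481 with 45, Gm17019 with 44, Gm21119 with 42, Gm21083 with 40 and C130026I21Rik with 37. These genes lie in crowded clusters on chromosomes 1, 5, 8, 11 and Y. No distal region lay within 50 kb of 2026 genes (9.26%).

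The density of regions differed between chromosomes and followed that of genes. The 19 autosomes carried 30.6 ± 3.65 regions per Mb (SD), from 25.2 to 38.7. The X chromosome carried 14.9 and the Y chromosome 1.88. Of the 171 regions on the Y, 70 lay beyond 90 Mb, near its end, and 50 of them in a single 100 kb window from 90700001 to 90800000. Across the 20 chromosomes other than Y, regions per Mb correlated with protein-coding genes per Mb (Pearson r = 0.747, permutation p = 7e-05, adjusted p = 0.000105; Spearman rho = 0.874, permutation p = 1e-05, adjusted p = 1.5e-05). Without chromosomes 11 and 7, which are farthest from the median gene density, r was 0.733 and rho 0.853. Of 3 relations computed, that for distal regions alone gave r = 0.604 (permutation p = 0.0048) and that for the autosomes alone r = 0.822 (permutation p = 3e-05).

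**Figure D5:**
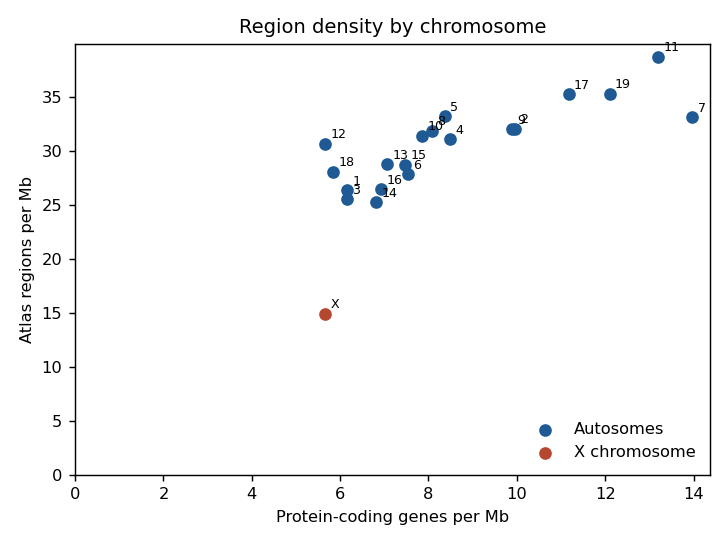
Atlas regions per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for the 19 autosomes (blue) and the X chromosome (red), each point labelled with its chromosome. The autosomes lie between 25.2 and 38.7 regions per Mb and the X chromosome at 14.9.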

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

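No paired analysis was possible because the atlas holds no value per library, and for the same reason the planned tests between groups, their alternatives with each replicate left out, and any statement about depth were not made. The motif alternatives and the use of the outermost start site alone were not run either, since only outer gene limits were used. Of 273 alternatives run for tested results, 246 kept direction and side of the threshold, 12 lost a call, 2 gained one and 13 changed direction, each of these in a list with no call in either setting. The number of lists called, a tally without a test, was equal to the reported one in 19 of 30 cases. For gene ends it was 7 or 8 higher and 3 to 5 lower, and for distal regions 5 to 7 higher and 2 lower. The share of regions at gene ends stayed between 16.9% (500 bp) and 26.5% (all gene types), above placements in each case. The rotated atlas, matched lists for gene ends, regions anywhere in the gene, the set without crowded windows, matching on density alone and neighbours counted as 1 gene were chosen after seeing the data. For gene ends, extension to 2 kb gave feeder fibroblast genes 50% (adjusted Fisher's exact p = 0.157), and the stricter set gave endoderm genes 33.3% (0.0437, gained) and G1/S genes 79.2% (0.0726). Against matched lists, in permutation tests, chromatin architecture genes had 91.7% (0.0720). With regions anywhere in the gene they had 100% (0.266), feeder genes 63.6% (0.246) and ectoderm and neural genes 95% (0.0012, gained). For distal regions, G1/S genes had a mean of 3.54 in 25 kb windows (0.0768) and trophoblast genes 10.5 in 100 kb windows (0.0836) and 6.81 with matching on density alone (0.0731). Histone genes had 4.68 with no matching (0.631) and with density alone (0.269), and 4.84 with neighbours counted as 1 gene (0.189). They had 2.95 without the regions of crowded windows (0.990), where the genes in these windows were kept and lost regions by construction. Changes of direction at gene ends were found for ectoderm and neural genes within 500 bp (50%, to lower), trophoblast genes within 2 kb (68.8%, to higher) and mesoderm genes against matched lists (50%, to higher). With regions anywhere in the gene, mesoderm (75%), endoderm (77.8%), trophoblast (81.3%) and Hox genes (66.7%) changed to higher. For distal regions, chromatin architecture (3.04, to lower) and Hox genes (2.18, to higher) changed in 25 kb windows, endoderm genes with 2 kb left out (3.67, to lower), ectoderm and neural genes with density alone (4.40, to lower), and Hox genes without crowded windows (3.72, to higher) and with neighbours counted as 1 gene (3.82, to higher). The cause of these changes was not tested.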

Other observations

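Gene classes outside the fixed lists were compared with protein-coding genes in 23 sets chosen after the data were seen. Of 408 tRNA genes, 289 (70.8%) had a region within 1 kb of an end, against 21.2% when moved by 20 kb and 62.0% of protein-coding genes (Fisher's exact test, adjusted p = 0.00028). Long noncoding RNA genes had one in 31.5% of cases and microRNA genes in 18.2%, against 16.7% and 12.8% when moved. The snoRNA genes had one in 11.4% and snRNA genes in 11.2%, against 8.13% and 8.67% when moved. Pseudogenes had one in 8.12%, and 9.42% when moved. The rRNA genes were at 50.8%, and at 41.3% when moved, and did not pass the test against protein-coding genes (adjusted Fisher's exact p = 0.0701).

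Among protein-coding families, shares were high for genes of the mitochondrial ribosome (Mrpl and Mrps, 96.0%), translation initiation (Eif, 94.6%), the proteasome (Psm, 91.7%), the cytosolic ribosome (Rpl and Rps, 89.5%) and zinc finger proteins named Zfp (87.8%). They were low for hair keratin-associated proteins (Krtap, 1.79%), the X-linked Rhox homeobox genes (6.06%), beta-defensins (Defb, 7.14%) and keratins (Krt, 18.4%). The collagen genes (Col, 47.7%) did not pass the test (adjusted Fisher's exact p = 0.0643).

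Of the tests below, that of X chromosome regions by width, that of crowded windows without tRNA or rRNA genes and that of list members with and without a region at an end were chosen only after the result was seen. The design names no group that bears on the 3 patterns, so no biological explanation was tested.

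The first pattern was the crowding of 1099 regions (1.43%) into 38 windows of 100 kb with 20 or more regions each, none of which held a core pluripotency gene. A crowd of protein-coding gene ends was argued against, since 10.1% (8.46 to 12.02%) of these regions lay at such ends, against 20.7% elsewhere. Ends of tRNA and rRNA genes were not counted, and 7 of the 38 windows held genes of these types. A crowd of those ends was therefore not tested. For reads shared between near-identical copies, the measure fixed beforehand came out against the explanation, with predicted or pseudogene entries making up 31.3% of 323 reference genes (26.5 to 36.5%) against 48.2% elsewhere. That measure was set aside only after this value was seen, because 40.2% of the 323 entries were tRNA or rRNA genes, against 0.687% elsewhere, and these are multi-copy genes that it counted as single ones. In the 31 windows without such genes the share was 55.1% (46.8 to 63.2%) against 48.5%, an interval that includes the other share, so shared reads may contribute but cannot be told apart from other causes with gene names alone.

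The second pattern was the low density on the X chromosome. Fewer genes do not account for it, since the X departed from the autosomal line by -12.2 regions per Mb, with 27.1 expected, a larger departure than the 4.01 of chromosome 7, the largest among the autosomes. Multi-copy genes are not the whole cause, since 61.3% (57.5 to 64.9%) of X genes had a region at an end after predicted genes and multigene families were left out, against 70.7% on autosomes, although the gap was wider with all genes, at 46.4% against 63.5%. A lower read depth on the X may contribute, since the ratio of X to autosomal density was 0.439 (0.404 to 0.477) in the narrowest of 4 equal classes of regions and 0.573 (0.533 to 0.617) in the widest. On the Y chromosome, 0 of 7 genes with X partners had a region at an end (Ddx3y, Eif2s3y, Kdm5d, Usp9y, Uty, Zfy1 and Zfy2), against 5 of their 6 X partners, with Zfx the exception. None of these Y genes had a region touching the gene either, and 1 of all 256 Y genes had a region at an end. The number of X copies in these cells is not given in the labels.

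The third pattern was the absence of regions at the ends of 11 genes in the 8 lists with high shares. Outer limits of the reference that are not the start in use are a candidate explanation: 81.8% of these genes (9 of 11) held a region inside the gene, over 1 kb from both ends and at least as wide as the 525 bp median of gene-end regions, against 18.6% (22 of 118) of members of the same lists that had a region at an end and were at least as long as the shortest of the 11 (Fisher's exact p = 3.8e-05), although the 11 were longer, with medians of 32.7 and 18.9 kb. The comparison fixed beforehand, with adult tissue genes, decides nothing, since 13 of those 19 genes held no inner region of any width. The widest inner region lay 1.13 kb from the nearer end in Actb, 1.35 in Rad21, 2.49 in Egr2, 5.95 in Ccnd3, 6.40 in Nr5a2, 7.78 in E2f2, 8.44 in Ywhaz, 20.4 in Nipbl and 34.1 in Esrrb, and the genes without a wide inner region were Axin2 and Bmp4. Transcript starts were not used here, and a wide region inside a gene need not lie at a start, so the explanation stays open.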
